A study of Xenopus laevis with 6 samples.

How the data were processed

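Gene expression was measured on Affymetrix Xenopus laevis Genome version 2.0 arrays, which read each transcript with a set of short oligonucleotides (a probe set). The table used here has 6 columns, each under the name of 1 sample of whole Xenopus laevis embryos at Nieuwkoop and Faber stage 10.5, the early gastrula. Per the labels, 3 samples came from embryos injected with an Ext1 morpholino (an antisense oligonucleotide against Exostosin 1, a glycosyltransferase that elongates heparan sulfate chains) and 3 from embryos injected with a mispaired control morpholino. Embryos were injected at the 2-cell stage with 20 ng of morpholino, and each RNA sample was made from a pool of 5 embryos.

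The deposited values are intensities on a linear scale with 2 decimals. MAS5, the Affymetrix algorithm that summarises a probe set into 1 signal, is named in the submitters' processing notes. Its version, its scaling target, its detection calls and any filter are not given in the sources used here. The table has 32635 probe sets, of which 96 are Affymetrix controls. Of the other 32539, the platform annotation gives 1 gene symbol for 15495 and several for 279. The remaining 16765 are unnamed here. For 15384 probe sets with 1 symbol, the gene ID was found in a RefSeq gene list and the symbol was taken from there, changed or not. Suffixes L and S mark the gene copies of the 2 subgenomes of this allotetraploid frog. No probe sequences or genome were used, so it was not tested whether a probe set separates the copies.

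Before any test, the 6 columns were compared with each other. For each ordered pair of columns, the range of factors was computed that turns one column into the other for every probe set, given that each deposited value is rounded and its true value lies within 0.005 of it. If 1 factor lies in the range of all probe sets, the columns are proportional within rounding. On simulated columns with a noise SD of 0.15 on the log2 scale, at least 32445 of 32635 probe sets fell outside, and on simulated proportional columns 0 did. All 30 ordered pairs of the deposited columns were proportional within rounding. The 6 columns were therefore counted as 1 profile, given as the mean of the 6 columns, with n = 1 and no error. No group was assigned to this profile.

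The test planned before the data were examined was a limma fit (lmFit and eBayes, limma 3.58.1 in R 4.3.3) on log2 intensities, with the replicate number as a block, since the series text says that paired samples were compared. Probe sets with a mean log2 value at or above the 40th percentile were to be tested, with Benjamini-Hochberg adjustment and a threshold of 0.05. This fit was run to document what it returns on proportional columns. Its values are a property of the column factors and of rounding. Neither they nor those of other settings fixed beforehand are results on Ext1. In simulated arrays with 200 probe sets changed by 2 on the log2 scale, the same code recovered 100% of them and called 13 others among 19523 tested. The noise SD was 0.15 on the log2 scale, and the changed probe sets were drawn from the brighter ones. Such a large change only checks that the code runs as intended, and does not measure its sensitivity to smaller changes. The planned gene list tests (camera and fry), the dorsal minus ventral shift, the agreement between pairs and the agreement between gene copies were left out, because ratios between these columns differ between probe sets only through rounding. Whether the replicate numbers pair the samples was not checked, for the same reason.

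The genes named were fixed before the data were examined: every ext1 probe set, and a list of dorsal, ventral and germ layer genes at the probe set with the highest mean. The parts of that rule that rank genes by their change could not be applied. For 17 gene lists, also fixed beforehand, the number of gene copies was counted whose signal lay above the highest of the 17 Affymetrix Tag control probe sets (24.4). This floor was chosen after the data were seen, and it is a rough guide, since each probe set has its own background. The number of arrays limits the precision, and here it is 1 profile. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used.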

Results

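The series was designed to ask what loss of Exostosin 1 (Ext1), an enzyme of heparan sulfate chain elongation, does to gene expression in the early gastrula of Xenopus laevis, with the dorsal-ventral pattern as its stated subject. The labels put 3 samples in a control morpholino group and 3 in an Ext1 morpholino group, each a pool of 5 embryos at stage 10.5. The signal table does not allow this comparison. Its 6 columns held 1 expression profile, multiplied by a different constant in each column, so the table used here holds no separate values for the control and the Ext1 morpholino embryos. Whether the arrays themselves were measured separately cannot be read from it.

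Relative to the first control, the constant was 0.9911 for the second control and 1.0188 for the third. It was 0.9894, 1.0239 and 1.0213 for Ext1 morpholino samples 1, 2 and 3. With 1 constant per column, 0 of 32635 probe sets departed from the first control by more than the rounding of the last decimal. This held for the 96 Affymetrix control probe sets as well, which include bacterial spike-in transcripts added apart from the embryo RNA. Over the 5511 probe sets with a signal above 1000 in the first control, the log2 ratio of a column to that control had an SD of at most 3.4e-06. Median signals ran from 110.07 in Ext1 morpholino sample 1 to 113.91 in Ext1 morpholino sample 2, and differed by the same constants.

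**Figure D1:**
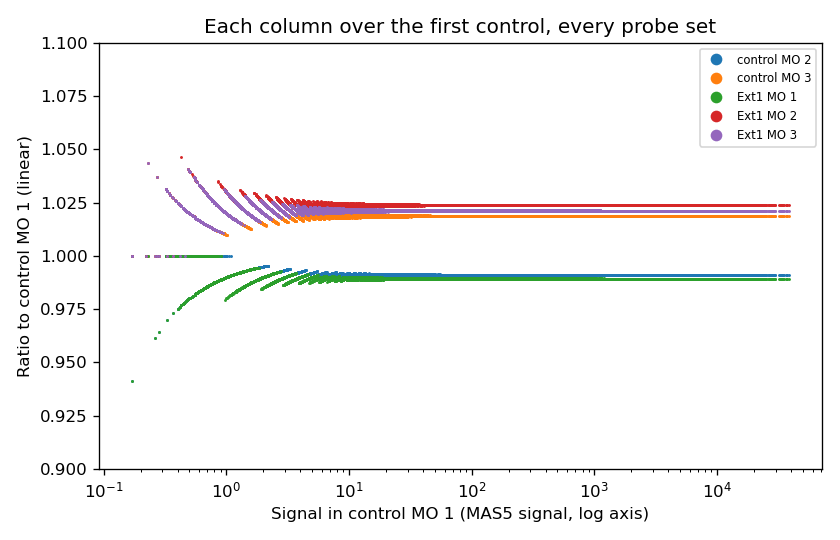
Ratio of each of the other 5 columns to the first control (vertical axis, linear) against the signal in the first control (horizontal axis, MAS5 signal, log axis), with 1 point per probe set. Each column lies on a flat line at its own constant, between 0.9894 and 1.0239, and the curved fans at low signal are the steps of values rounded to 2 decimals.

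For the effect of the Ext1 morpholino, the fit returned the same ratio for every gene, within rounding. Among 19523 probe sets the log2 difference, Ext1 morpholino minus control, lay between 0.0116 and 0.0119. This range holds the mean difference of the column constants on the log2 scale. The paired limma fit called 0 probe sets at an adjusted p under 0.05, with a lowest adjusted p of 0.53 and 0 probe sets at an unadjusted p under 0.05. In all 3 pairs, 0 probe sets differed by 2-fold or more. These counts are not evidence that the morpholino left gene expression as it was, because no separate measurement of the 2 groups was in the columns.

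The targeted gene was measured by 6 probe sets. For ext1.S the profile signals were 526.99, 345.6, 228.68, 64.3 and 25.29, and for ext1.L the signal was 195.02. The ext1.S probe set at 25.29 was close to the highest Tag control (24.4), and the filter left it out of the planned fit. The labels do not say whether the morpholino acts on translation or splicing, and its effect on ext1 RNA cannot be read from proportional columns. The log2 difference of the brightest ext1.S probe set was 0.0117, the value shared by the other genes. Of 27 measured gene copies of heparan sulfate synthesis, 26 had a signal above the highest Tag control (24.4), as did 8 of 10 copies of proteoglycan cores that carry heparan sulfate. The same floor was passed by 9087 of all 11303 named gene copies at their brightest probe set (80.4%), and by 23424 of 32539 probe sets (72.0%), so most lists pass it as most genes do. No list was tested against this share.

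What remains is the level of each probe set in a profile that cannot be assigned to either group. It carries no error, and levels of different probe sets cannot be ranked against each other, since each has its own response. Genes of the dorsal organizer had signal in it: chrd.1.S, which encodes the BMP antagonist chordin, was at 2217.94. The homeobox genes gsc.L and gsc.S were at 972.71 and 817.27, the secreted antagonists cer1.S and dkk1.S at 5447.53 and 598.23, and nog.L, which encodes the BMP antagonist noggin, at 229.92. In the organizer and dorsal list, 34 of 39 gene copies lay above the Tag control floor.

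Ventral genes of the BMP pathway also had signal. The ligand genes bmp4.S and bmp4.L were at 2157.5 and 230.93, and the BMP-responsive homeobox genes ventx2.1.L, ventx2.1.S and ventx1.2.S at 5060.69, 3705.39 and 1201.57. The gene copies ventx1.1.L and ventx1.1.S were at 544.55 and 658.38. The secreted ventral factor szl was at 262.62 for its S copy and 197.96 for its L copy, and bambi.L, a decoy receptor gene, at 963.87. The transcription factor genes msx1.L, msx1.S and gata2.L were at 756.40, 427.98 and 952.11, and the BMP target genes id3.S and id3.L at 13517 and 7055.86. In this list, 39 of 40 gene copies lay above the floor.

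Among mesoderm genes, tbxt.S and tbxt.L, which encode Brachyury, were at 5913.99 and 5330.91, wnt8a.L at 3696.9, fgf8.L at 2021.17 and cdx4.L at 1041.8. The myogenic gene myod1 was at 133.77 for its S copy and 59.14 for its L copy. The endoderm genes sox17a.L and sox17a.S were at 1451.43 and 1243.75, and the mesendoderm genes mix1.S and mix1.L at 3527.74 and 2968.18. Ectodermal genes were represented by sox2.L at 1173.27, sox3.S at 12260 and sox3.L at 9788.95. In surface ectoderm, tfap2a.L and tfap2a.S were at 8053.47 and 6025.1, and the keratin genes krt12.4.L, krt12.4.S and krt12.5.S at 1491.76, 213.77 and 870.70. Signals above the floor were counted for 50 of 62 gene copies of the mesoderm list and 33 of 35 of the endoderm list. For the neural list the count was 34 of 44, and for the surface ectoderm list 31 of 36. Lists share members, such as cer1 in the organizer, mesoderm and endoderm lists, so their counts are not independent. The neural share was slightly below that of all named gene copies (80.4%), and this difference was not tested.

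Several probe sets of 1 gene often gave different levels. For fgf8.L they ranged from 2.51 to 2021.17, and for ventx1.1.L from 4.29 to 544.55, so a level belongs to its probe set and not to the gene.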

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

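Every value in this part comes from columns that are 1 profile times a constant, and none of it bears on Ext1. The values reflect the column constants and rounding. The count with array weights comes from the same columns, and also rests on weights that did not converge. The planned paired limma fit called 0 probe sets, and so did the fit with no replicate block (0), the offset of 20.2 before the log, no filter, the stricter filter, an intensity trend with robust settings, the ordinary paired t-test, a threshold of 0.10, the 2-fold requirement and each fit that left out a pair. Median scaling called 34 probe sets and quantile normalization 68. Once the constants were removed, the called probe sets had log2 differences of at most 0.00018 and 0.00014, which is the size of rounding. With array weights, where limma warned that convergence was not reached, 19523 of 19523 probe sets were called; the cause was not tested. The log2 difference of the brightest ext1.S probe set turned from 0.0117 to -1.65e-05 under median scaling, and ran from -0.0059 to 0.0253 when a pair was left out. Without replicate 2 it was -0.0059. Probe sets at 2-fold or more in all pairs numbered 0 under every alternative run, 1.5-fold included. Taking any other column as the base, chosen after seeing the data, also left 0 probe sets outside rounding. Other splits of the samples were not counted. The planned list tests, the dorsal minus ventral shift, the agreement between pairs, and the values of the named genes other than ext1, were not run under the alternatives. A paired analysis of the embryos was not possible because the paired columns hold the same profile.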

Other observations

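Counts above the Tag control floor (24.4) for the other lists describe the same single profile. They were 29 of 30 measured gene copies for maternal and oocyte transcripts, 14 of 14 for germ plasm, 57 of 58 for cell cycle and replication, and 45 of 52 for gastrulation movement and matrix. For signalling targets, the counts were 25 of 28 for FGF/MAPK, 25 of 30 for Wnt/beta-catenin, and 14 of 23 for Hedgehog and retinoic acid. For lists that bear on side effects of morpholinos, they were 27 of 30 for the p53 response and 28 of 41 for the innate immune and stress response. Over all named gene copies it was 9087 of 11303, a larger share than in the Hedgehog and retinoic acid list and in the innate immune and stress list. These differences were not tested. Neither group can be set against the other for any of them.

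The tests in this paragraph were all chosen after the proportional columns were seen. If the 6 columns held the values of separate hybridisations, each scaled by MAS5, probe sets would vary between columns by more than rounding. The largest SD of the log2 ratio over bright probe sets was 3.371e-06, which argues against this origin of the columns. It says nothing on whether separate arrays were run. A single profile written to every column with a factor of its own is a description of the 30 of 30 proportional pairs, not a separate test of it. Its simplest version, 1 column as deposited multiplied to give the others, was tested by taking each column as exact: 0 of 30 ordered pairs were then reproduced, with 7866 to 8541 probe sets outside rounding. A candidate source that remains open is a shared profile with more decimals than the table prints. Whether such a profile came from 1 sample or from several was not tested. Nor was it tested whether the columns became proportional in the deposit or later, on the way to the table used here. The trimmed mean signal (2% at each end) was 500.11 in the first control and between 494.79 and 512.06 in the other columns. These means differed by the column constants, so they are not separate evidence. The scanner files of the 6 arrays were not analysed here, and a comparison of Ext1 morpholino with control embryos would need them or another copy of the table.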
